A study of Mus musculus with 6 samples.

How the data were processed

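RNA was measured on 6 Affymetrix oligonucleotide arrays, 1 for each of 3 FACS-sorted cell populations of mouse skin (basal epidermis, hair follicle matrix and outer root sheath, ORS) in each of 2 genotypes, wild type (WT) and Ezh1/Ezh2 double knockout (2KO). The labels give an age of 14 days, a mixed C57B6 and CD1 background, and RNA of female mice for the 2KO basal epidermis and of both sexes for the other 5 samples. They do not say how many mice gave each sample, or whether the 3 samples of a genotype came from the same mice. Labelling was a biotin in vitro transcription from the 3-prime end, per the labels' protocols.

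The deposited values are intensities on a linear scale, 1 MAS5 signal per probe set and array, with MAS5 named in the submitters' processing notes and background subtraction of the images in the series text. The version of MAS5 and its detection calls were not given in the sources used here. The series text names the MOE430A 2.0 array in one place and MOE430v2 in another, and the table holds 45101 probe sets, 64 of them control probe sets. The deposited signals of each array have a 2% trimmed mean of 500, so each array had been scaled to one total before deposit. The median signal was 72.6 and 78.4 on the WT and 2KO basal epidermis arrays, 76.2 and 92.5 on the matrix arrays, and 83.1 and 99.0 on the ORS arrays. The values are not centred per gene, and each column is 1 sample, so the direction of a ratio follows from the labels. Scaling to one total fixes the sum of the signals, so that a shift of most genes in one direction cannot be seen in these values, and a rise of abundant transcripts lowers all others.

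Genes were named from the platform's annotation, which lists 35890 of the probe sets, 34958 with 1 gene and 932 with several; 9160 probe sets are not listed and stayed unnamed. Of the gene identifiers, 99.4% were found in the RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. That table served for names and for the order of neighbouring genes only, and no coordinates were used. Control probe sets and probe sets with several genes were left out. Each gene was represented by the probe set with the highest mean log2 signal over the 6 arrays, which gave 18193 genes.

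The deposited signals were used without further scaling, because the trimmed means lay within 1.1-fold of each other. Signals below the median of all probe sets over the 6 arrays, 83.2, were raised to that floor, and the log2 ratio of 2KO over WT was taken within each cell type. A gene was called higher or lower when the ratio reached 2-fold, the fold the series text uses. A gene with both signals below the floor counted as not measured in that pair, and a ratio with 1 side at the floor is a lower bound, written as at least N-fold. With 1 array per group there is no spread between replicates within a cell type, and no gene was tested and no p-value is given. A fit with the 3 cell types as pairs was not made, because it would take cell types as replicates. The number of arrays limits the precision.

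Gene lists, 30 in number with 728 genes, were fixed before the data were examined. Of their genes, 650 were matched to a probe set naming 1 gene here, among them Nckap1, which was wrongly matched in the place of H19. For a list with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size, drawn from measured genes within 20 bins of mean signal, and its percentile is given. A percentile of 0 or 100 means that 0 of the random lists were as low or as high. One factor per array moves a list and its random lists alike. A member below the floor in WT is measured only if its 2KO signal is higher, and one below it in 2KO only if it is lower, so the floor fixes the sign of such members. The percentiles describe these arrays and are not p-values.

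The genes named were chosen by a rule set before the data were examined. Ezh1, Ezh2, Cdkn2a, Cdkn2b and Cdkn2c were always named. In each cell type the 10 genes with the largest and the 10 with the smallest ratio were eligible, as were the 10 with the largest and the 10 with the smallest mean ratio among those at least 2-fold the same way in all 3 cell types. Up to 4 members of each list per cell type with the largest differences were eligible too, together with sex markers. Symbols that are only clone names were passed over, which happened for 1 gene. Other members named beside a small count were chosen after their values were seen.

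The calling of genes was tested on simulated data, in which each WT array was copied with log2 noise of SD 0.2 and additive noise of SD 15. In each cell type 100 genes were changed by each of 2 folds, and all 18193 genes were then called. The changed genes were drawn from those with a WT signal more than 2-fold above the floor. Changes from a WT signal near or below the floor were not tested. In basal epidermis 98.0% of 3-fold and 94.0% of 6-fold changes were called, in matrix 96.0% and 96.0%, and in ORS 91.0% and 91.0%. Of unchanged genes 12, 12 and 15 were called. The noise of the real arrays is unknown without replicates.

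Alternatives fixed before the data were examined were no floor, a floor at the 25th or the 75th percentile, quantile normalization, scaling to a common median, loess within each pair, the mean of all probe sets of a gene, leaving out cross-hybridising probe set classes, counting probe sets in place of genes, and thresholds of 1.5-fold and 3-fold. Scaling to the hybridisation controls, a count without the matrix pair, a matrix count without genes richer in the other WT populations, and list results over members above the floor in WT and over all matched members were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.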

Results

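Gene expression was compared between mice labelled WT and mice labelled Ezh1/Ezh2 2KO. The sample titles do not say in which cells the 2 genes were deleted. Ezh1 and Ezh2 are the catalytic subunits of Polycomb repressive complex 2 (PRC2), which methylates histone H3 and keeps developmental genes silent. Cells were purified by FACS from the skin of 14-day-old mice as 3 populations. These were basal epidermis, the progenitor layer of the epidermis; matrix, the dividing cells of the hair bulb that make the hair shaft and its inner sheath; and ORS, the outer layer of the follicle. Each of the 6 groups had 1 array. No difference below has a replicate check, and genes are described as at least 2-fold higher or lower in 2KO than in WT. Between 47.7% and 53.1% of probe sets per array lay above the floor of 83.2 signal units.

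The targeted genes were lower on every 2KO array. The brightest Ezh2 probe set read 2563 in WT and 432 in 2KO basal epidermis (5.93-fold lower), 2151 and 378 in ORS (5.69-fold lower), and 3578 and 1725 in matrix (2.07-fold lower). The brightest Ezh1 probe set was at least 4.82-fold lower in basal epidermis, 3.54-fold lower in matrix and at least 4.57-fold lower in ORS. The other 3 Ezh1 probe sets were below or close to the floor in WT, so that the mean over all Ezh1 probe sets was less than 2-fold lower. The labels do not say which exons were deleted, and whether these probes lie inside the deleted parts is unknown. The other 9 PRC2 members of the list lay within 2-fold in all cell types, except that Jarid2 was 2.33-fold higher in ORS. Of 15 measured members of the sister complex PRC1, Phc1 was 4.04-fold and Bmi1 2.11-fold higher in basal epidermis, Phc1 was 2.43-fold higher in ORS, and 0 differed by 2-fold in matrix. The PRC2 list had medians of 0.04, -0.15 and -0.06 in basal epidermis, matrix and ORS (percentiles 45.1, 10.3 and 34.8), the first of which was negative after scaling to a common median (-0.07) and to the hybridisation controls (-0.02). The PRC1 list had medians of 0.04, 0.07 and 0.12 (percentiles 55.4, 65.8 and 79.9), all of which were negative under the same pair of scalings (-0.07, -0.21 and -0.13 with the common median).

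**Figure D1:**
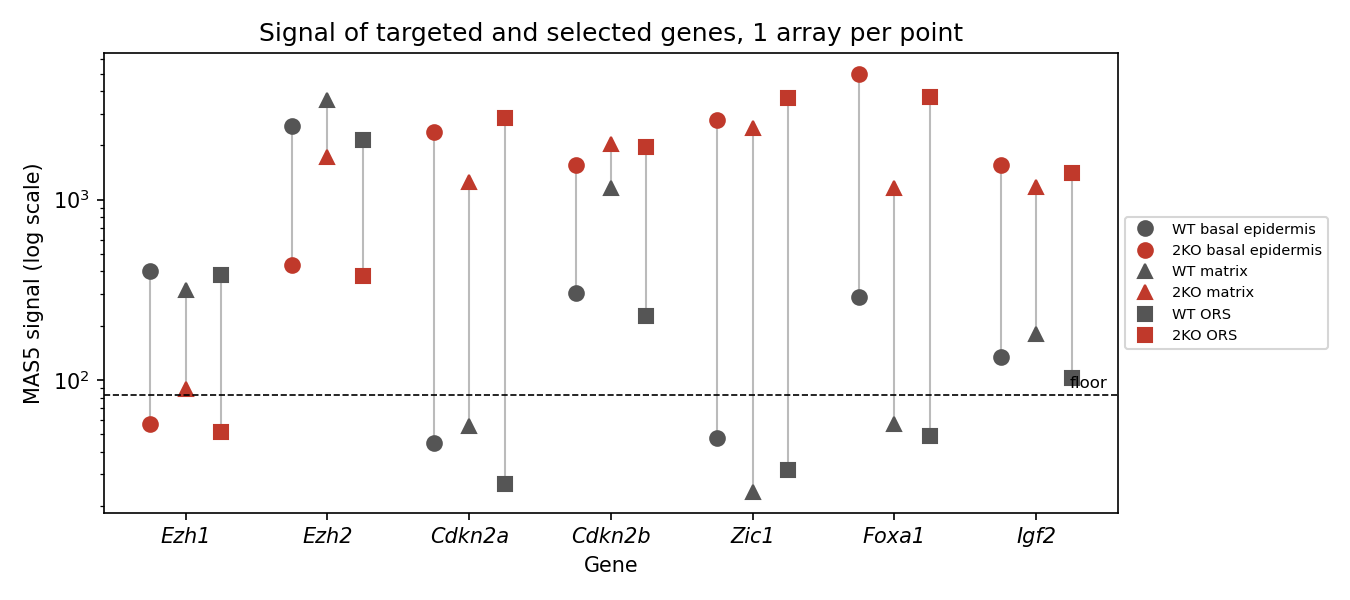
MAS5 signal (log axis) of Ezh1, Ezh2, Cdkn2a, Cdkn2b, Zic1, Foxa1 and Igf2 on each of the 6 arrays, 1 point per array, with WT in grey and 2KO in red, and the floor as a dashed line. The 2KO point lies below the WT point in every pair for Ezh1 and Ezh2, with the smallest gap for Ezh2 in matrix (3578 against 1725), and above it for the other 5 genes.

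In basal epidermis 760 genes were at least 2-fold higher and 471 at least 2-fold lower in 2KO, of 11527 genes measured. In matrix the counts were 1053 and 189 of 11661, and in ORS 979 and 570 of 11994. The WT signal lay below the floor for 32.2%, 30.8% and 29.4% of the higher genes, and the 2KO signal for 13.4%, 12.2% and 14.4% of the lower genes. The share of calls that were higher, 61.7% in basal epidermis, 84.8% in matrix and 63.2% in ORS, depended on the scaling. It was 52.2%, 55.4% and 39.0% after scaling to a common median, which moved the median log2 ratio of measured genes to -0.07, -0.24 and -0.24 from 0.04, 0.03 and 0.01. After scaling to the hybridisation controls it was 55.9%, 14.4% and 44.5%, with medians of -0.02, -0.64 and -0.18. Differences are therefore relative to the total signal of each array.

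**Figure D2:**
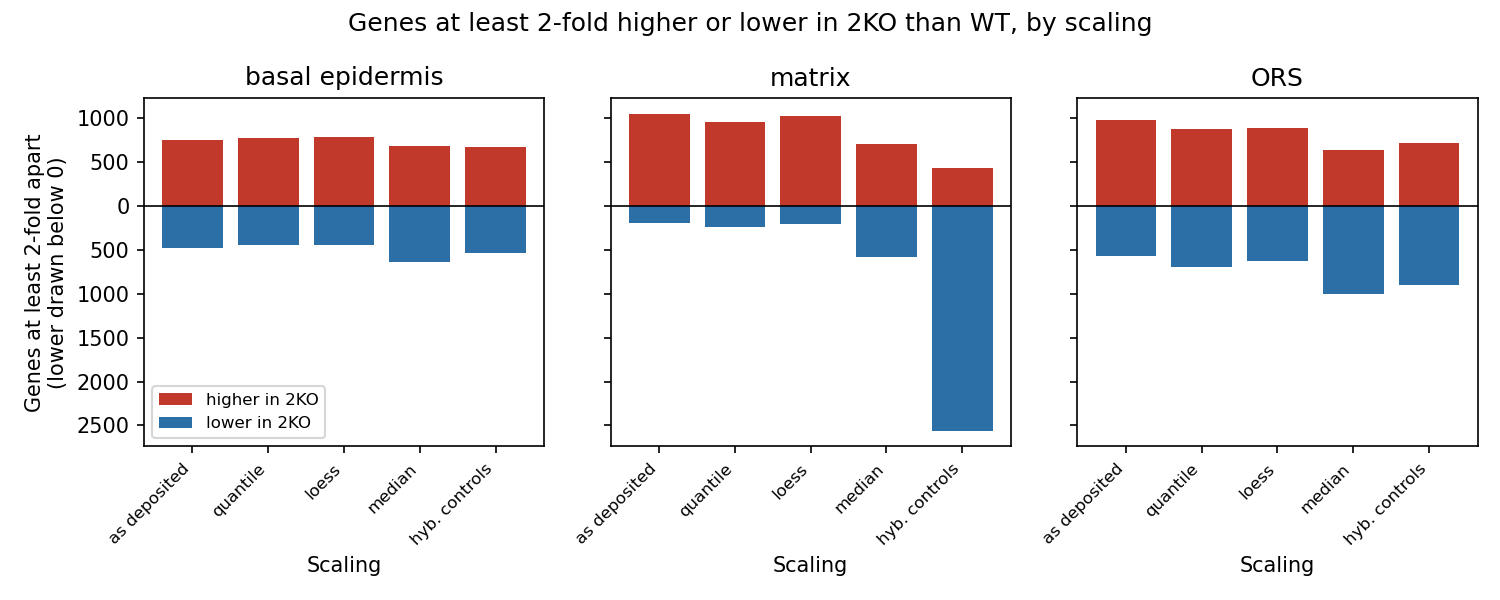
Number of genes at least 2-fold higher (red) or lower (blue, drawn below 0) in 2KO than in WT for each cell type, under 5 scalings of the arrays. With the deposited scaling the matrix pair has 1053 higher and 189 lower genes, and with scaling to the hybridisation controls 432 and 2559.

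A core of genes was higher in all 3 cell types. Cdkn2a, which encodes the cell cycle inhibitors of the INK4/ARF locus, was at least 28.7-fold higher in basal epidermis, at least 15.1-fold in matrix and at least 34.1-fold in ORS. Zic1, a transcription factor of neural and mesodermal development, was at least 33.4-, 29.9- and 44.0-fold higher, and Foxa1, a factor of endodermal organs, 17.3-fold, at least 13.9-fold and at least 44.7-fold. The other leading genes were Zdbf2, Foxd1, Calcb, Cpt1c, Tac1, Igf2 and Efhd1. Igf2, an imprinted growth factor, was 11.5-, 6.53- and 13.6-fold higher, and Tac1, which encodes the substance P precursor, 17.1-fold, at least 8.06-fold and 7.62-fold. In all, 212 genes were at least 2-fold higher in all 3 cell types, where independent lists would share 4.96. Lower in all 3 were 19 genes against 0.252, led by Sdr42e1, Elovl3, Ezh1, Ezh2, Hoxb6, Krtap15, Krtap8-1, Rarres1, Slc16a10 and Hoxb2. After scaling to the hybridisation controls 115 genes were higher and 64 lower in all 3. Hoxb2 was 3.83-, 2.55- and 4.20-fold lower, and Elovl3, a fatty acid elongase of sebaceous glands, 4.26-, 2.30- and 9.37-fold lower.

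Across genes, the log2 ratios of basal epidermis and ORS had a Pearson r of 0.558 (Spearman 0.434), matrix and ORS 0.452 (0.450), and basal epidermis and matrix 0.222 (0.115). These are 3 correlations across genes, which are not independent replicates. Basal epidermis and ORS shared 381 higher and 179 lower genes, where independent lists would share 58.4 and 21.8. Each pair of arrays has its own WT array, but mice could be shared within a genotype.

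Among 7 cell cycle inhibitors, Cdkn2b, the neighbour of Cdkn2a, was 5.13-fold higher in basal epidermis and 8.60-fold higher in ORS, and 1.74-fold higher in matrix. Cdkn2c differed little, at 995 in 2KO against 869 in WT basal epidermis, 1193 against 1449 in matrix, and 841 against 889 in ORS. Cdkn1a was 2.35-fold higher in matrix and 2.56-fold in ORS, and the imprinted Cdkn1c was 7.04-fold higher in ORS. Cdkn1b was 2.23-fold lower in basal epidermis and 2.06-fold lower in ORS. The median log2 ratio of the list was 0.20, 0.78 and 1.36 in basal epidermis, matrix and ORS, at percentiles 81.3, 99.4 and 100 of random lists.

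Many developmental regulators of other lineages were higher in each cell type. Of 48 measured in basal epidermis 17 were higher and 1, Pou3f1, was lower; in matrix 18 of 51 were higher and 0 lower; in ORS 27 of 53 were higher and 1, again Pou3f1, lower. Besides Zic1 and Foxa1 these included the hindlimb gene Pitx1 (at least 9.35-fold higher in basal epidermis and 5.59-fold in ORS), Pou3f3 (at least 4.75-fold, basal epidermis), Irx5 (4.70-fold) and Tbx3 (at least 4.49-fold) in matrix, and Tbx15 (at least 5.84-fold, ORS). The median log2 ratios were 0.71, 0.60 and 1.0, each at percentile 100, but 33, 38 and 35 of the measured members had a WT signal below the floor and were measured only through a higher 2KO signal, which fixes their sign. Of the 15, 13 and 18 members above the floor in WT, 4, 5 and 4 were higher, with medians of 0.11, 0.52 and 0.30 at percentiles 77.9, 99.8 and 98.9. Counted over all 94 matched members, the 17, 18 and 27 higher genes exceeded the highest count of 10000 random lists drawn from all genes (14, 13 and 13). Most folds are lower bounds, and with a floor at the 75th percentile the basal epidermis median was -0.022.

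Hox genes, which set position along the body axis, went both ways. Of paralog groups 1 to 8, 7 of 14 measured genes were lower in basal epidermis, 5 of 11 in matrix and 7 of 14 in ORS, with medians of -0.95, -0.88 and -0.98. Hoxd8 was the 1 gene of these groups that was higher, 8.90-fold in basal epidermis and 3.94-fold in ORS. Of paralog groups 9 to 13, 9 of 11, 9 of 12 and 8 of 12 genes were higher and 0 lower, with medians of 1.68, 1.46 and 1.41. Only 2, 3 and 3 of the measured genes of groups 9 to 13 were above the floor in WT, so that the others could not be lower. Of those above it, 1, 1 and 0 were higher and 0 lower. Hoxa5 was 4.27-fold lower in basal epidermis and Hoxb6 4.51-fold lower in matrix, while Hoxd10 was at least 10.4-fold and Hoxd13 at least 9.30-fold higher in matrix. The signs of the medians of both sets of groups were the same under all 5 scalings. For groups 9 to 13 the floor fixed the sign of most measured genes, so this could hardly have come out otherwise. The list as a whole had 10 higher and 7 lower of 25, 9 and 5 of 23, and 9 and 7 of 26, with medians of -0.24, 0.26 and -0.05 at percentiles 0.42, 89.9 and 12.5. The basal epidermis median was 0.0020 with a floor at the 75th percentile and 0.080 without cross-hybridising probe sets. Over members above the floor in WT the medians were -0.82, -0.64 and -0.88, and over all measured members the matrix median was -0.01 after scaling to a common median and -0.40 after scaling to the hybridisation controls.

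**Figure D3:**
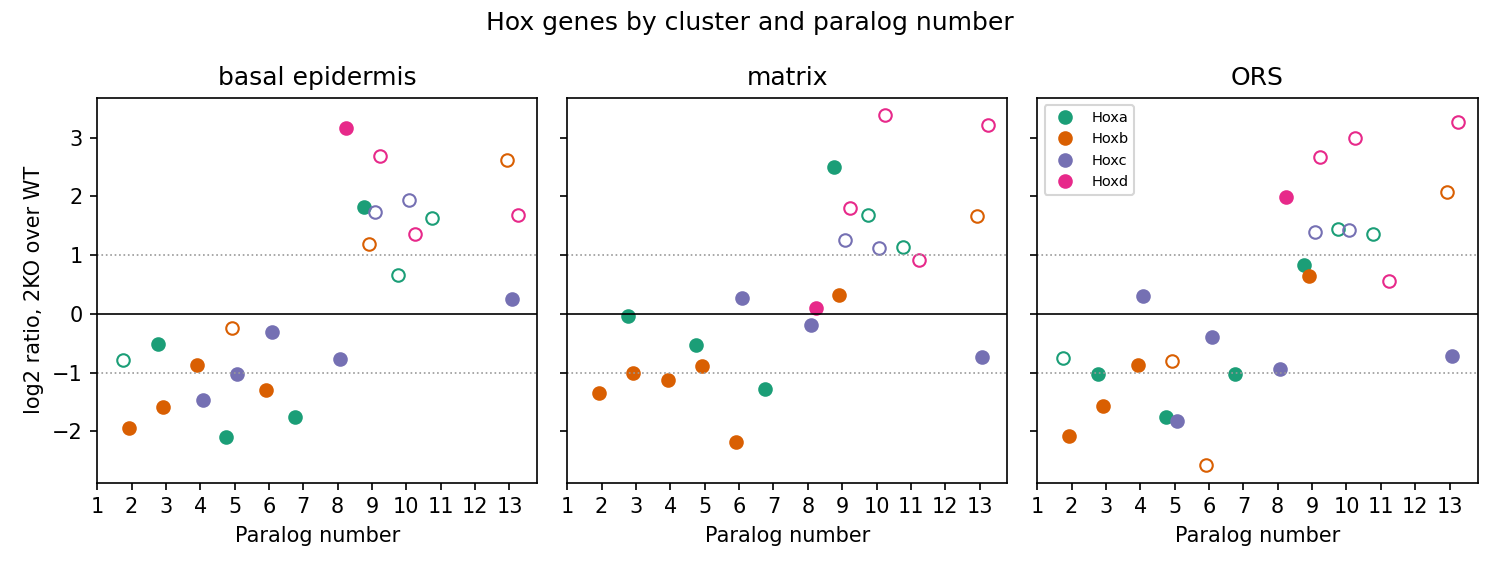
Log2 ratio of 2KO over WT for each measured Hox gene against its paralog number, for the 3 cell types, coloured by cluster. Open symbols are bounds with 1 array below the floor, and dotted lines mark 2-fold. Of paralogs 9 to 13 in matrix 9 of 12 lie above the upper line, and of paralogs 1 to 8 in matrix 5 of 11 lie below the lower line.

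Imprinted genes were also higher, with 5 of 16 measured members higher and 1 (Ascl2) lower in basal epidermis, 6 of 15 higher in matrix and 9 of 16 higher in ORS. Ndn was 9.59-fold higher in basal epidermis, Plagl1 9.72-fold and the noncoding Meg3 8.32-fold in matrix, and Grb10 6.20-fold in ORS. The medians were 0.61, 0.78 and 1.59, at percentiles 100, 100 and 100 after rounding. The measured members include Nckap1, another gene that took the place of the listed H19 when symbols were matched. It had log2 ratios of 0.03, 0.03 and -0.09, so it adds to the members measured and not to those higher. H19 itself was not measured.

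In basal epidermis the simple epithelial keratin Krt7 was 19.6-fold higher, Gpx2 16.1-fold, Gapdhs 16.7-fold, and Atg9b, Calml4 and the Polycomb family gene Sfmbt2 at least 24.2-, 20.5- and 13.5-fold. Krt77, a keratin of eccrine ducts and epidermis, was 67.8-fold lower (7616 against 112), Il22ra2 24.8-fold, Bbox1 at least 23.6-fold, Abi3bp at least 22.0-fold, Fcgbp 13-fold, Cyp2b10 12.4-fold, Oas1f 12.3-fold and Il1r2 12.2-fold lower.

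Basal layer genes, such as Krt5 and Krt14, stayed within 2-fold in basal epidermis (0 of 12). Of early differentiation genes 4 of 16 were higher, among them Calml3 (5.29-fold) and Grhl3 (4.16-fold), and 2 lower, Krt77 and Dsg1a (4.22-fold). Of cornified envelope genes 11 of 27 were higher, with Sprr2h 6.46-fold, Lce3c at least 6.28-fold and Sprr1b 4.90-fold, and 4 lower, with the protease gene Klk7 6.38-fold lower. The median of that list, 0.44 at percentile 99.9, was -0.12 over the 22 members above the floor in WT, -0.018 with a floor at the 25th percentile and -0.010 without cross-hybridising probe sets. Medians of the basal and early lists were -0.21 and 0.34, at percentiles 1.46 and 99.4.

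Cell cycle genes were higher in basal epidermis, with 40 of 43 above 0, a median of 0.54 at percentile 100, and 6 at least 2-fold higher, among them Cdc25c (2.66-fold), Ube2c (2.61-fold), Ccnd1 (2.33-fold) and Birc5 (2.32-fold). Genes of the list of p53 targets and apoptosis were higher in 8 of 20 cases and lower in 0, with Eda2r 6.27-fold, Ccng1 4.38-fold and Zmat3 3.96-fold higher (median 0.48, percentile 100). Wound and stress genes were higher in 9 of 22 cases, with Ereg 8.02-fold, Slpi 7.46-fold and Krt6b 4.95-fold, and 1, Il33, was lower (median 0.69, percentile 100). AP-1 and immediate early genes were lower, with Egr2, Junb, Fosb, Zfp36 and Ier2 between 2.11-fold and 3.12-fold lower and 0 of 19 higher (median -0.54, percentile 0). Interferon and MHC class I genes were lower in 8 of 20 cases, with Usp18 at least 6.35-fold, Irf9 3.00-fold and Psmb8 2.66-fold (median -0.73, percentile 0). Immune cell markers were lower on the same array, with 3 of 14 at least 2-fold lower, Ptprc, Cd74 and Lyz2 (median -0.60, percentile 0.01).

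Genes of the ORS and follicle stem cells in basal epidermis included 6 of 30 higher, with Wif1 7.54-fold, Tcf7l1 3.78-fold and Lhx2 3.69-fold, and 3 lower, Postn (2.74-fold), Id2 and Id3 (median 0.28, percentile 99.7, and -0.093 with a floor at the 75th percentile). Genes of matrix, inner root sheath and hair shaft were lower in 14 of 32 cases and higher in 3 (median -0.73, percentile 0), with the sheath keratin Krt25 13.9-fold, the shaft keratin Krt35 at least 10.7-fold and Krt32 7.80-fold lower. This does not hold for matrix-rich genes at large. Of 135 genes at least 4-fold richer in WT matrix than in both other WT populations, those measured here had a median of 0.31. They were picked for a low WT signal outside matrix, which favours higher ratios. Of signalling genes of the WNT, SHH, BMP and NOTCH pathways 2 of 31 were higher, Wif1 and Lef1 (3.14-fold), and 4 lower, among them Bmp2 (3.34-fold) and Id1 (2.98-fold), with a median of -0.03 at percentile 27.0, which was 0.01 after loess and after quantile normalization.

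In matrix the alarmin S100a9 was at least 33.4-fold higher, the ORS and sebaceous duct keratin Krt79 18.1-fold (19517 against 1077), Krt6a 17.7-fold, the chemokine Cxcl2 13.6-fold, Crabp2 14.2-fold, and Car3 and Homer2 at least 19.4- and 15.9-fold. Lower were the hair shaft genes Krtap15 (10.2-fold) and Krtap7-1 (4.52-fold), Padi4 (5.51-fold), Sptssb (4.73-fold), Atp13a4 (4.71-fold), Slc7a11 (at least 4.63-fold), Csta1 (4.56-fold) and Sdr42e1 (4.57-fold).

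Of 30 ORS and stem cell genes 14 were higher and 0 lower in matrix, with Sox9 12.6-fold and Nfatc1 9.44-fold, and 5 of 12 basal layer genes were higher, with Lamb3 3.18-fold and Krt14 2.87-fold. Their medians were 0.91 and 0.85, both at percentile 100. Early differentiation genes were higher in 6 of 15 cases, with Krtdap 9.31-fold and Calm4 4.54-fold (median 0.88, percentile 100). Cornified envelope genes were higher in 7 of 27 and lower in 2, Flg and Tgm3, with Sprr1b 6.25-fold higher and a median of 0.53 at percentile 99.9, which was -0.078 after scaling to the hybridisation controls. Of the matrix, sheath and shaft list 8 of 39 genes were lower, with Padi3 3.23-fold and Msx2 2.79-fold, and 3 higher, Krt73 (3.67-fold), Shh (2.86-fold) and Krt84 (median -0.44, percentile 0). Of all 1053 higher genes, 648 (61.5%) were at least 2-fold richer in WT ORS or WT basal epidermis than in WT matrix, and 405 were not.

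Wound and stress genes were higher in 16 of 20 cases in matrix and 0 were lower (median 2.01, percentile 100). Markers of cells outside the epithelium were higher on the same array. Skeletal muscle genes were higher in 7 of 11 cases, with Acta1 13-fold and Myl1 at least 10-fold (median 1.20, percentile 100), and 8 of the 11 were below the floor in WT. Immune genes were higher in 10 of 15, with H2-Eb1 9.11-fold and Tyrobp at least 4.20-fold (median 1.36, percentile 100). One of the 10, Epcam (10596 against 4851), was bright on all 6 arrays and so does not mark cells outside the epithelium here. The immune list counts Epcam in every pair. Fibroblast genes were higher in 13 of 19, with Col6a1 6.39-fold and Vim 3.90-fold (median 1.45, percentile 100). Genes of the list of p53 targets and apoptosis were higher in 6 of 19, with Bcl2l11 4.20-fold and Ccng1 3.41-fold (median 0.83, percentile 100). Cell cycle genes had 1 of 43 higher, Ccnd1 (2.07-fold), and 35 below 0, with a median of -0.23 at percentile 0.06. AP-1 genes had 3 of 19 higher, Fosl1 (2.80-fold), Dusp1 (2.65-fold) and Fosb (2.13-fold), with a median of 0.47 at percentile 100 after rounding, which was -0.22 after scaling to the hybridisation controls. Of the signalling genes 6 of 38 were higher, with Sfrp2 at least 4.83-fold, and 2 lower, Hes1 and Wnt10b (median -0.11, percentile 4.58). Interferon genes had 0 of 15 at 2-fold in either direction, with a median of 0.09 at percentile 59.2 that was negative after quantile normalization (-0.005), scaling to a common median (-0.11) and scaling to the hybridisation controls (-0.53).

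In ORS the genes with the largest differences besides Foxa1 and Zic1 were Zdbf2 (at least 32.6-fold higher), Serpina3n (25-fold), Pcp4 (24.3-fold), the neuropeptide gene Calcb (21-fold), the WNT inhibitor Wif1 (21-fold), the peptidase gene Mme (at least 17.0-fold) and Foxd1 (at least 16.8-fold). Lower were Krt77 (at least 23.3-fold), Clca3a2 (20.3-fold), Adtrp (18.8-fold), Cyp17a1 (18.6-fold), Cmah (18.1-fold), Adh1 (17.4-fold), Avpr1a (15.5-fold), Aadac (15.1-fold), Scin (14.5-fold) and Defb6 (14.4-fold).

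Sebocyte genes were lower in ORS, with 10 of 14 at least 2-fold lower, all 14 below 0 and a median of -1.60 at percentile 0. Far2 was 12.9-fold, Elovl3 9.37-fold, Scd3 8.91-fold and Cidea 7.13-fold lower. In basal epidermis 3 of 13 were lower, Elovl3, Far2 (at least 4.02-fold) and Scd1 (median 0.29, percentile 95.7), and in matrix 2 of 12 were lower, Fabp4 (4.55-fold) and Elovl3, and 1, Dgat2, higher (median -0.12, percentile 12.7).

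Of the signalling genes 13 of 36 were higher in ORS and 1, Id1, lower (median 0.63, percentile 100). They included the SHH target Gli1 (6.17-fold) and the WNT pathway gene Lef1 (5.06-fold). Of the ORS and stem cell list 9 of 30 were higher, with Ltbp1 2.90-fold, and 3 lower, with Krt79 3.28-fold, and the median of 0.19 at percentile 98.8 was -0.064 after scaling to a common median and -0.011 after scaling to the hybridisation controls. Matrix, sheath and shaft genes were lower in 11 of 30 cases, with Krt25 7.79-fold and Krt35 7.11-fold, and higher in 5 (median -0.79, percentile 0). Genes at least 4-fold richer in WT matrix, picked for a low WT signal in ORS, again went the other way (median 0.42 of those measured). Cornified envelope genes were lower in 7 of 25, with Klk7 12.3-fold and Sprr1a 3.95-fold, and higher in 3 (median -0.31, percentile 0.5). Early differentiation genes had 1 higher, Krtdap, and 2 lower, Krt77 and Calm4 (7.58-fold), of 15 (median -0.25, percentile 3.89), and 0 of 12 basal layer genes differed by 2-fold. The basal layer median of 0.03 at percentile 55.8 was -0.01 after quantile normalization, -0.22 after scaling to a common median and -0.17 after scaling to the hybridisation controls.

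Genes of the list of p53 targets and apoptosis were higher in 8 of 20 cases in ORS, with Bcl2l11 4.54-fold and Zmat3 2.53-fold (median 0.90, percentile 100). Cell cycle genes had 2 of 43 higher, Ccnd1 (3.48-fold) and Ccnd2 (2.26-fold), with a median of 0.08 at percentile 88.0 that was -0.13 after scaling to a common median and to the hybridisation controls. Wound and stress genes were higher in 7 of 21, with Cxcl2 9.94-fold and Ereg 9.49-fold, and lower in 2, Lcn2 and Il33 (median 0.59, percentile 100). Fibroblast genes were higher in 6 of 17, with Fbln2 7.42-fold and Dcn 4.58-fold (median 0.80, percentile 100). Interferon genes had 2 of 18 lower, Usp18 and Psmb8 (median -0.50, percentile 0.01), and AP-1 genes 1 of 19 lower, Egr2 (median -0.23, percentile 0.46).

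Some genes of Merkel cells, the touch receptor cells of the skin, were higher in every pair. Of 20 matched members 9 were measured in each pair, of which 7 were higher in basal epidermis, 7 in matrix and 6 in ORS. Cck was at least 12.2-fold, Isl1 at least 9.02-fold, Ncam1 7.57-fold and Krt18 7.01-fold higher in basal epidermis. Krt8 was at least 5.11-fold higher in matrix and Sox2 at least 6.10-fold in ORS. The medians were 2.61, 1.60 and 1.69, at percentiles 100, 100 and 100 after rounding. In basal epidermis 7 of the 9, in matrix 7 and in ORS 6 were measured only through a higher 2KO signal and could not be lower. The floor thus fixed the sign of these medians. It did not make their size, since the folds of such members are lower bounds.

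**Figure D4:**
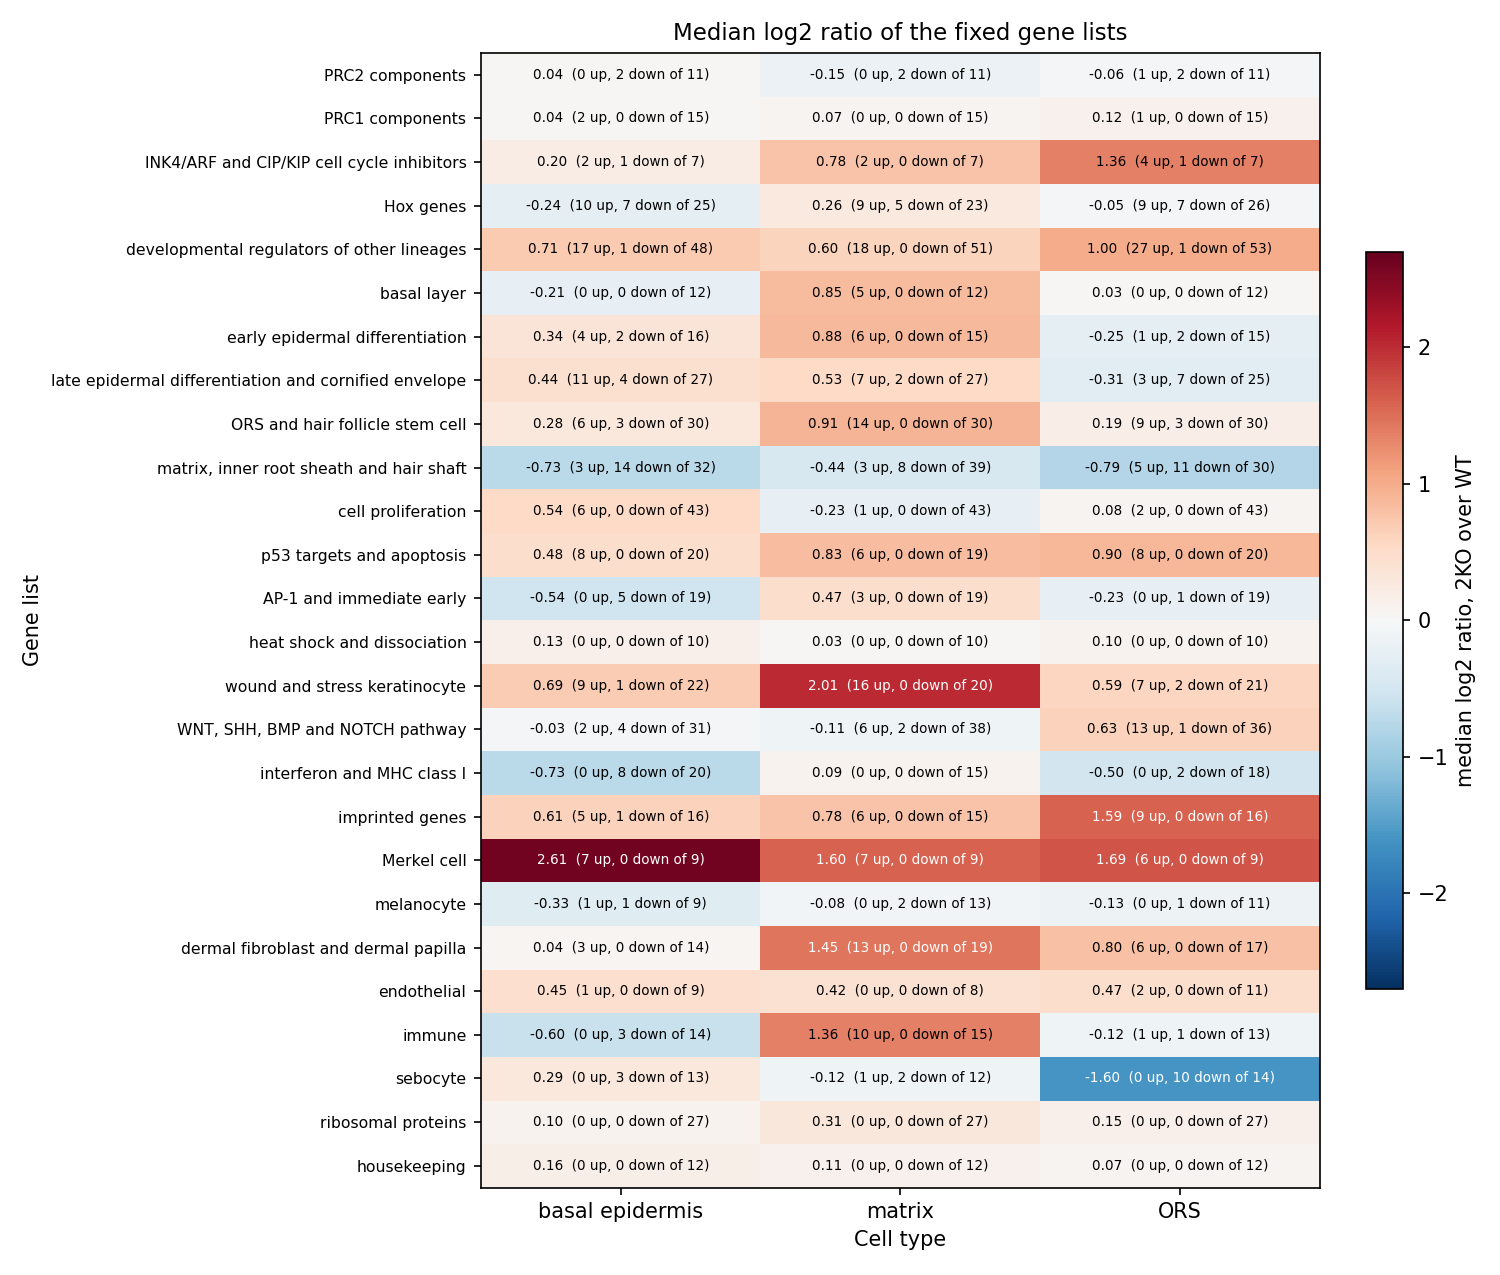
Median log2 ratio of 2KO over WT (colour and first number) for each gene list with at least 5 measured members in every cell type, with the numbers of members at least 2-fold higher (up) and lower (down) of those measured. Merkel cell genes in basal epidermis have the highest median shown (2.61) and sebocyte genes in ORS the lowest (-1.60).

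Fibroblast genes in basal epidermis had 3 of 14 higher, Fbln2 (9.37-fold), Col5a1 and Dcn, with a median of 0.04 at percentile 50.3 that was -0.02 after scaling to a common median and -0.07 with the hybridisation controls. Immune genes had 1 higher, H2-Eb1, and 1 lower, Lyz2, of 13 in ORS (median -0.12, percentile 19.8). Melanocyte genes had Gpnmb higher and Mitf lower of 9 in basal epidermis (median -0.33, percentile 3.73), Gpnmb (3.00-fold) and Dct lower of 13 in matrix (-0.08, 11.9), and Tyrp1 lower of 11 in ORS (-0.13, 17.8). Endothelial genes had Egfl7 higher of 9 in basal epidermis, 0 of 8 in matrix, and Cldn5 and Egfl7 higher of 11 in ORS, with medians of 0.45, 0.42 and 0.47 at percentiles 93.0, 86.0 and 92.4, and the matrix median was -0.09 after scaling to the hybridisation controls. Muscle genes had 3 measured members in basal epidermis and 3 in ORS, with 0 differing by 2-fold. Schwann cell genes had Mal higher of 3 in basal epidermis, Pmp22 and Mbp higher of 5 in matrix (median 0.62, percentile 94.2), and 0 of 4 in ORS. The erythroid list rested on Car2 alone, 10.3-fold higher in basal epidermis, 2.54-fold lower in matrix and 3.04-fold higher in ORS. Heat shock genes (10 measured), ribosomal protein genes (27) and housekeeping genes (12) had 0 members at 2-fold in any pair. Their percentiles in basal epidermis, matrix and ORS were 65.2, 19.8 and 75.6 for heat shock, 57.8, 98.4 and 96.3 for ribosomal proteins, and 78.8, 53.6 and 69.0 for housekeeping genes. In matrix and ORS the medians of these 3 lists, all positive, were negative after scaling to the hybridisation controls (in matrix -0.66, -0.38 and -0.58). In ORS and, for heat shock and housekeeping, in matrix they were negative with the common median too. Loess (-0.04) and quantile normalization (-0.06) also turned the heat shock median in matrix, quantile normalization turned the ribosomal median in ORS (-0.01), and in basal epidermis the ribosomal median was -0.007 after loess and -0.008 with the common median.

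The basal layer list and the matrix, sheath and shaft list told matrix from both other fractions in both genotypes, and the remaining lists did not in every contrast. The basal layer list had a median log2 ratio of basal epidermis over matrix of 2.37 in WT and 1.65 in 2KO, but did not tell basal epidermis from ORS (0.38 in WT and 0.04 in 2KO). The matrix, sheath and shaft list had a median of ORS over matrix of -2.98 in WT and -2.72 in 2KO, and the ORS list 1.90 and 1.04. For basal epidermis over matrix, however, the ORS list had 0.59 in WT and -0.32 in 2KO. The cornified envelope list had a median of ORS over matrix of 0.39 in WT and -0.13 in 2KO. Early differentiation genes had a median of basal epidermis over ORS of 1.44 in WT and 1.92 in 2KO, and the cornified envelope list 0.06 and 1.08.

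Sex markers differed between genotypes. The Y-linked gene Eif2s3y read 1194 on the 2KO basal epidermis array, whose label names female mice only, against 580 on its WT array of both sexes, and was 2.06-, 3.08- and 3.12-fold higher in 2KO in basal epidermis, matrix and ORS. Kdm5d was 2.61- and 3.28-fold higher in basal epidermis and matrix, and Uty 2.00-fold in matrix. Xist is expressed from the inactive X chromosome, and its probe sets differed. The brightest read 7837 in 2KO against 9426 in WT basal epidermis, 4482 against 8962 in matrix, and 9927 against 8358 in ORS. A second read 882 against 2793, 619 against 3558, and 3042 against 2234, and the dimmest 250 against 493, 85.5 against 570, and 284 against 493.

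Array controls differed as well. The mean log2 signal of the hybridisation controls was higher in 2KO by 0.06 in basal epidermis, 0.69 in matrix and 0.20 in ORS. The 3-prime over 5-prime log2 ratio of the labelling control Dap was higher in 2KO by 0.82, 1.49 and 1.27, and that of Thr by 0.55, 1.21 and 1.16. For the Actb control probe sets the ratio was higher by 0.03, 0.33 and 0.22, and for Gapdh by 0.21, 0.42 and 0.12. Of the other labelling controls, Phe was higher by 0.25, 0.48 and 0.20, and Lys was lower in basal epidermis (-0.28) and higher by 0.03 in matrix and 0.23 in ORS. The labelling controls thus did not all move alike.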

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

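The tests in this part were chosen after the result was seen, except the loess test of the Hox genes. With 1 array per group, no difference between cell types was tested. Among genes picked by the naming rule, those given first drew attention because their 2KO array was at least 2-fold higher than WT in one cell type and at least 2-fold lower in another. The log2 ratio in matrix exceeded that in ORS by 5.10 for Calm4, 6.13 for Defb6, 2.34 for Dgat2, 5.47 for Klk7, 5.89 for Krt79 and 3.94 for Sprr1a. The ratio in matrix exceeded that in basal epidermis by 2.62 for Fosb, 7.55 for Krt77 and 3.35 for Postn, and by at least 6.41 for Il1r2, 4.33 for Krt73 and 2.97 for Ptprc, where 1 signal was below the floor. The ratio in basal epidermis exceeded that in matrix by 4.71 for Car2, 2.94 for Gpnmb and at least 5.81 for Sptssb. For Bmp2 the ratio in ORS exceeded that in basal epidermis by 3.30. Over all genes, 12 were higher in basal epidermis and lower in matrix, where independent lists would share 9.97, and 54 the reverse, against 36.95. For basal epidermis and ORS these counts were 13 and 10, against 35.5 and 35.8. With matrix higher and ORS lower there were 56, against 45.9, and the reverse 6, against 13.5.

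Markers of ORS, basal layer, muscle, immune cells and fibroblasts were higher together on the 2KO matrix array, and Ezh2 was least reduced there. Ezh2 read 1725 in 2KO matrix against 432 in 2KO basal epidermis and 378 in 2KO ORS, so a share of those cells would not raise it. Why it was least reduced was not tested. Of 45 measured markers of muscle, immune cells and fibroblasts, 25 lay above the floor on the WT matrix array and so could go either way, and 25 of 25 lay above 0 (21 after scaling to the hybridisation controls), which restates the pattern; Acta1 reached 1153 and Vim 4405, and 1 of the 45 is on another list. Of endothelial and Schwann cell markers above the floor there, which other cells of the skin would bring along, 5 of 8 lay above 0, so muscle, immune and dermal cells left in the FACS sort and higher expression of these genes in matrix cells cannot be told apart. For a larger share of ORS cells, 372 genes at least 4-fold above their WT matrix signal on both ORS arrays implied a median share of 24.5% (quartiles 14.9% and 35.9%), which would lower matrix-rich genes by a log2 of -0.40. The 135 matrix-rich genes had a median of -0.70 (bootstrap interval over genes -0.86 to -0.56), lower than that share gives, so ORS cells in the sort and a change of the matrix cells themselves cannot be told apart, since genes picked for a high WT matrix signal drop for any reason; of the 1053 higher genes, 63 were at least 2-fold above all 4 ORS and basal epidermis arrays, which a mixture with those cells would not give.

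Many Hox genes of paralog groups 1 to 8 were lower and many of groups 9 to 13 higher in 2KO, the latter mostly with a WT signal below the floor. A trend of the ratio with signal was tested by loess. After it 16 ORS genes still were at least 2-fold apart in the direction of their end of the cluster. Of these, 8 were lower genes of groups 1 to 8, of 14 measured, and 8 were higher genes of groups 9 to 13. With the deposited scaling 0 of the 3 ORS genes of groups 9 to 13 above the floor in WT were higher. The floor thus set the direction of the higher genes, and the test does not decide for them. The bound of the test was set for both ends together, so it does not apply to the 8 lower genes alone. All measured genes of groups 1 to 8 lay above the floor in WT. In basal epidermis, matrix and ORS their medians were -0.95, -0.88 and -0.98 before loess and -0.92, -0.94 and -1.045 after it. Loess takes out a trend with signal and left these medians about as low, which argues against such a trend for groups 1 to 8. For groups 9 to 13 it stays open. Skin from a more posterior body position in 2KO may also give this Hox pattern. The limb genes do not decide, with Pitx1 of the hindlimb higher on 3 of the 2KO arrays and Tbx5 of the forelimb higher on 2. There were 0 arrays where Tbx5 was also above the floor in WT. The body position is not in the labels, so it cannot be told apart from a biological effect of the genotype on Hox genes, a hypothesis these arrays leave open.

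The labelling controls Dap and Thr, but not Lys (-0.28 in basal epidermis), had a higher 3-prime over 5-prime ratio on all 3 2KO arrays, so this yield goes with genotype. As the cause of most higher genes through the scaling it is argued against in basal epidermis and ORS. There the hybridisation controls, added after labelling and taken as equal in amount, were lifted by a log2 of 0.06 and 0.20 (SD over 9 probe sets 0.10 and 0.08). A call needs a log2 of 1. The bound that this lift had to stay under was chosen with its values known. The higher genes had medians of 1.43 and 1.42, which lie above 1 by their selection. In ORS, higher calls still fell from 979 to 640 with the common median, so the argument is weaker there. In matrix the lift was 0.69, and after scaling to these controls 41.0% of the higher genes stayed 2-fold higher there, against 89.5% in basal epidermis and 73.6% in ORS, so for the other matrix genes the scaling and higher expression cannot be told apart. For the lower genes, Actb and Gapdh ratios were higher by at most 0.42 on the log2 scale, too little to settle it, and matrix, the pair with the largest value, had the fewest lower genes with the deposited scaling (189) but the most with the hybridisation controls (2559), so lower yield and lower expression cannot be told apart. Loss of Ezh1 and Ezh2 remains an open biological explanation, not tested apart from this.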

How the results depend on the processing

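Scaling to the hybridisation controls, the count without the matrix pair, the use of list members above the floor in WT or of all matched members, and the matrix count without genes richer in other WT populations were chosen after the result was seen. With 1 array per group no result has a replicate check. The labels give no replicate numbers that pair the arrays, and a fit with the 3 cell types as pairs was left out, since it would take cell types as replicates. Ezh2 stayed lower on each 2KO array in all settings run, and was 2-fold lower in all but matrix after loess (-1.0, just inside). No named value at least 2-fold apart took the other sign in any setting. A change of floor cannot turn a sign, nor can 1 factor per array that changes a ratio by under 2-fold, as here. For the floors and for scaling to the common median or the hybridisation controls this was thus fixed in advance. Of these values, 109 of 291 were under 2-fold with a floor at the 75th percentile (52 of them 0, with both sides at the floor). There were 39 with the mean of all probe sets, 23 with the hybridisation controls and at most 13 in each other setting. Of 895 list medians under alternatives, 84 took the other sign, 12 of them for lists whose main median lay outside the central 95% of random lists.

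The counts below are in the order higher and lower in basal epidermis, higher and lower in matrix, higher and lower in ORS, higher and lower in all 3. Without a floor they were 2796, 1727, 3320, 1276, 2878, 1722, 619 and 96. With a floor at the 25th percentile they were 1637, 828, 2149, 436, 1834, 935, 453 and 39, and at the 75th percentile 235, 235, 311, 79, 337, 282, 39 and 4. At 1.5-fold they were 1706, 1284, 2087, 1004, 1958, 1570, 468 and 84, and at 3-fold 306, 169, 416, 34, 377, 192, 64 and 2. Fewer or more genes pass by construction of these settings. For probe sets in place of genes the first 6 were 1200, 1124, 1707, 683, 1985 and 1111, and 53 were lower in all 3. The mean of all probe sets gave 502 higher in basal epidermis, 673 in matrix and 129 in all 3. Scaling to a common median gave 574 lower in matrix, 640 higher and 1002 lower in ORS, and 33 lower in all 3. Scaling to the hybridisation controls gave 432 higher and 2559 lower in matrix, 899 lower in ORS, and 115 higher and 64 lower in all 3. Both scalings lower the 2KO arrays by 1 factor each. Without the matrix pair 381 genes were higher and 179 lower in both remaining cell types, and without genes richer in other WT populations 405 were higher in matrix. The share of higher calls also moved by over 10 percentage points with a floor at the 75th percentile, to 50% in basal epidermis, for probe sets, to 51.6% in basal epidermis and 71.4% in matrix, and in matrix without a floor, to 72.2%, and at 1.5-fold, to 67.5%.

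The log2 ratio of Ezh1 was 0, 0 and 0 with a floor at the 75th percentile, which lies above its WT signal. It was -0.57, -0.48 and -0.55 with the mean of all probe sets, most of which lie below or close to the floor in WT. Pearson r for basal epidermis and matrix, basal epidermis and ORS, and matrix and ORS was 0.157, 0.310 and 0.246 without a floor, 0.273, 0.517 and 0.421 at the 25th percentile, and 0.0765, 0.459 and 0.432 at the 75th. With the mean of all probe sets it was 0.435 for matrix and ORS. Among lists outside the central 95% of random lists, the medians that changed sign were those of the cornified envelope list in basal epidermis (-0.018 with a floor at the 25th percentile, -0.010 without cross-hybridising probe sets, -0.12 over members above the floor in WT) and in matrix (-0.078, hybridisation controls), and of the Hox list in basal epidermis (0.0020 with a floor at the 75th percentile, 0.080 without cross-hybridising probe sets). With a floor at the 75th percentile the developmental regulators (-0.022) and the ORS list (-0.093) changed sign in basal epidermis. The ORS list changed sign in ORS (-0.064, common median, and -0.011, hybridisation controls), and AP-1 genes (-0.22) and ribosomal proteins (-0.38) did in matrix with the hybridisation controls. The cause was not tested.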

Other observations

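The tests of neighbouring and of X-linked genes in this part were set before their results were seen, and the counts of lower neighbours were looked at after.

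Merkel cell genes that were higher in 2KO did not include several of its best known markers. The lineage factor Atoh1 read 26.2, 31.5 and 60.4 on the 2KO arrays of basal epidermis, matrix and ORS, below the floor of 83.2, and so did Rab3c, Chga, Syp and Piezo2. Krt20 read 100 in 2KO basal epidermis, just above the floor, against 19.3 in WT. In the same arrays Isl1 read 750, 253 and 562 and Sox2 509, 324 and 507. The transcription factors Isl1 and Sox2 were thus well above the floor on arrays where Chga, Syp and Rab3c were below it.

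Matrix was closer to the other populations in 2KO than in WT. The Pearson r of floored log2 signals across probe sets between basal epidermis and matrix was 0.924 in WT and 0.958 in 2KO, and between matrix and ORS 0.932 and 0.962, while between basal epidermis and ORS it was 0.972 in WT and 0.965 in 2KO. Both higher values involve the 2KO matrix array.

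One hypothesis was that genes higher in 2KO lie next to each other on chromosomes, as genes silenced in one domain would. In ORS 58 neighbouring pairs with different symbol stems were both higher, against a median of 51 and an upper limit (of the central 95%) of 64 in 1000 redraws matched on signal, and in basal epidermis and matrix the counts of 31 and 69 also lay below their upper limits of 41 and 76. No excess was seen at this size. The 5 pairs higher in all 3 cell types were Col9a3 and Tcfl5, Ankrd6 and Rragd, Nkain1 and Sdc3, Shroom3 and Sowahb, and Plaur and Cadm4. Lower genes were neighbours more often than redraws in basal epidermis (23 against an upper limit of 18) and ORS (29 against 26), but not in matrix (2 against 5). Near-identical gene copies with unlike names were not excluded from these pairs.

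Another hypothesis was that X-linked genes are higher in 2KO, as a loss of silencing on the inactive X chromosome would give. The median log2 ratio of X-linked genes was 0.04, 0.03 and 0.01 in basal epidermis, matrix and ORS (343, 342 and 359 genes), at percentiles 41.6, 34.2 and 45.7 of 10000 matched autosomal lists, so no shift was seen. The differing shares of male and female RNA on the arrays limit this comparison.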
